A study of Mus musculus with 9 samples.

How the data were processed

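RNA from hearts of 12-week-old male mice was sequenced after TRIzol extraction, column purification and TruSeq library preparation. The 9 libraries form 3 groups of 3: wild-type mice given isoproterenol, OMA1 knockout mice left untreated, and OMA1 knockout mice given isoproterenol at 10 mg/kg per day from minipumps for 7 days. The knockout mice of the untreated group are described as non-treated, so pump implantation and drug were not separated. Untreated wild-type hearts were not analysed here, and for that reason no test of whether genotype changed the response to isoproterenol was possible.

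The authors name cutadapt, RSEM 1.17 and limma as their tools and GRCm38 as the genome build. The settings and the aligner are not given in the sources used here. The deposited values, in the unit signal, are normalized expected counts scaled to library size, 1 value for each of 13539 genes and each library. Each value was a whole number of reads times 1 step per library: within a tolerance of 0.02 reads, 100% of the values in the lower range were whole. The recovered reads came to 6.93e+06 to 1.22e+07 per library, and the column sums to 9.46e+05 to 1.02e+06. A floor of 3 reads over the 3 libraries of a group was used wherever a group was at 0, and it covers counting error only. Genes were left out of the deposited table by a rule not given in the sources used here.

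Values were taken as log2(value + 1). The 8543 genes with a value of at least 10 in at least 3 of the 9 samples were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, a spread shared by the 3 groups and a mean-variance trend. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. The fixed gene lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 3 tested genes out of 36 fixed. Beside each count of list members past the threshold over all genes, the count adjusted over the list alone is given where it differs. The lists cover cardiac remodelling, energy metabolism, mitochondrial upkeep, stress and immune responses, excitation, rhythm and markers of the cell types that heart tissue can hold. Gene positions, transcript lengths and GC content came from GENCODE release M21 on GRCm38, in which 13385 of the listed IDs were found; 8494 tested genes had a length and a GC content.

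The groups, comparisons, filter, tests, gene lists and the rule for naming genes were set before the data were examined. The rule names Oma1 and the 10 genes with the largest rise and the 10 with the largest fall that passed the threshold in each comparison with the treated knockout hearts, with every library of one group above every library of the other and a symbol that is not a predicted model. It adds the top 5 each way for treated wild-type against untreated knockout hearts and up to 4 members with the smallest p of each list described. It also names Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Postn, Atf4, Fgf21, Gdf15 and Opa1 whatever their p. Fgf21 is not among the genes listed, and Gdf15 lay below the minimum for testing.

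Alternatives covered the pseudocount, the filter, 3 further scalings of the samples, the form of the limma fit, the threshold, the samples in the fit, the replicate number as a block, the list test and each library left out in turn. After the data were seen, edgeR 4.0.16, DESeq2 1.42.0 and limma voom on the recovered reads were added, as was a correction of each library for transcript length and GC content with natural splines of 5 degrees of freedom. The closing section gives their effect. Some results for single genes are not reported here. The pipeline was tested on simulated data with 194 changed genes among 8420, where limma recovered 80.4% of 1.5-fold changes between the treated groups and 82.5% between the knockout groups, with 10 and 13 false calls. The simulated counts had no trend by transcript length or GC content, no outlying library and no correlation between genes. These rates may therefore not hold for the data. All p-values measure the spread between these samples; the labels give no animal numbers.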

Results

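Heart transcriptomes of wild-type mice given isoproterenol, untreated OMA1 knockout mice and OMA1 knockout mice given isoproterenol were compared, with 3 libraries per group. OMA1 is a stress-activated protease of the inner mitochondrial membrane that cleaves OPA1, the dynamin-like GTPase of inner membrane fusion. Isoproterenol is a β-adrenergic agonist that makes the heart work harder and remodel. Values are the deposited normalized counts, given as mean ± SD of n = 3 libraries, and log2 differences carry the standard error of the limma fit. Reads per library ranged from 6.93e+06 to 1.22e+07. Transcripts of the mitochondrial genome made up 36.7% to 37.3% of the signal in treated wild-type hearts and 33.9% to 34.6% in untreated knockout hearts. In treated knockout hearts they made up 38.2% to 42.5%, with replicate 2 the highest. On the first principal component, which held 61.7% of the variance, all 3 untreated libraries lay apart from the 6 treated ones. The second, with 17.6%, parted treated wild-type from knockout hearts.

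The knockout was visible in the transcript of Oma1 itself (ENSMUSG00000035069, chromosome 4, 103313812 to 103371868). Oma1 stood at 19.9 ± 2.16 in treated wild-type hearts, 7.42 ± 1.46 in untreated knockout hearts and 6.24 ± 0.502 in treated knockout hearts. In treated hearts the knockout lowered it by a log2 difference of -1.53 ± 0.14 (adjusted p = 4.7e-05; -0.88 with a pseudocount of 10). Knockout libraries kept 48 to 77 reads of the gene against 173 to 240 in wild-type libraries. Between the knockout groups Oma1 differed by -0.21 ± 0.14 (adjusted p = 0.24).

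**Figure D1:**
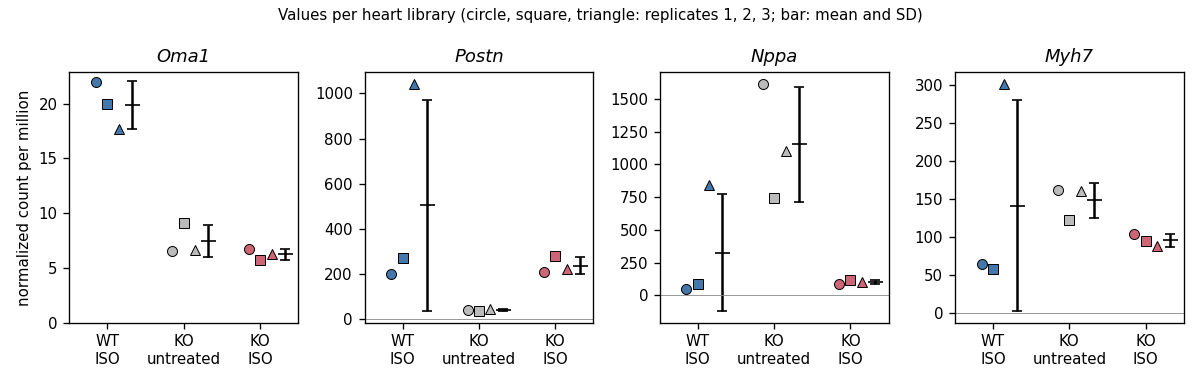
Normalized counts (y axis) of Oma1, Postn, Nppa and Myh7 in each heart library, by group (x axis); points are replicates, and bars give the mean and SD of n = 3. Oma1 is low in all 6 knockout libraries, and replicate 3 of the treated wild-type hearts is the highest of its group for Postn (1043), Nppa (842) and Myh7 (301).

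The first comparison asks how hearts without OMA1 differ from wild-type hearts when both are under adrenergic load. Treated knockout hearts held less mRNA for calcium handling, ion channels, the tricarboxylic acid cycle and mitochondrial shape, and more for respiratory chain subunits, endothelial cells and interferon-stimulated genes. Each of these list calls was lost with an estimated correlation (adjusted p = 0.89), and the median of the respiratory chain list fell from 0.25 to 0.09 after correction for transcript length and GC content. The most strongly lower genes included Hipk2, a nuclear kinase (53.1 ± 7.24 in wild-type, 17.9 ± 4.56 in knockout hearts), Slc8a1, the sodium-calcium exchanger of the heart (137 ± 4.06 and 49 ± 9.89), and Sgcd, a sarcoglycan of the muscle membrane (17.4 ± 2.44 and 6.57 ± 0.451). Pdpr, a regulatory subunit of pyruvate dehydrogenase phosphatase, Ppara, a nuclear receptor that drives fatty acid oxidation, Gpam, an acyltransferase of triglyceride synthesis, and Irs1, an insulin receptor substrate, had log2 differences of -1.27 ± 0.11, -1.16 ± 0.16, -1.13 ± 0.13 and -1.12 ± 0.19. Lnpep and Inpp4b differed by -1.25 ± 0.15 and -1.21 ± 0.18. The most strongly higher genes were Dynlt1b (0.611 ± 1.06 in wild-type, 15.7 ± 2.88 in knockout hearts; log2 difference 3.55 ± 0.44), Mid1 (1.94 ± 0.18) and Alad, an enzyme of haem synthesis (1.28 ± 0.10). Lgals4, Myh7b, Amy1, Lime1, Tcf15, Wnk4 and Echdc2 followed, with log2 differences from 1.28 down to 0.88. That of Tcf15 was 0.47 after correction for transcript length and GC content (adjusted p = 0.065). Dynlt1b and Amy1 belong to families of near-identical genes, between which reads can be shared. The log2 difference of Dynlt1b was 1.28 with a pseudocount of 10 and 4.57 by edgeR, since it lay near 0 in wild-type hearts. That of Mid1 was 1.25 with a pseudocount of 10. Lgals4, Myh7b, Amy1, Wnk4 and Echdc2 also stood higher in untreated knockout than in treated wild-type hearts. Their log2 differences there were 1.13, 0.96, 0.99, 0.93 and 1.07. They did not pass between the knockout groups, so their difference was not particular to treated knockout hearts. No other gene named in this paragraph met the rule of the closing section for genes that followed genotype.

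In all, 2379 of 8543 genes passed the threshold (27.8%), 1023 higher and 1356 lower in knockout hearts. Few differed by much, with 9 higher and 18 lower by at least 2-fold. Without treated knockout replicate 2, 1336 genes passed, and 1574 passed after correction for transcript length and GC content. Of the fixed lists, 10 passed, and none of these 10 did with an estimated correlation, where each had adjusted p = 0.89. No list of the 31 reached an unadjusted p under 0.05 by that camera setting.

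Calcium handling genes were lower as a group: 13 of 22 tested genes were lower and 0 higher (16 lower when adjusted over the list alone), with a median log2 difference of -0.35 (adjusted p = 2.1e-05; adjusted p = 0.89 with an estimated correlation). Besides Slc8a1, they included Ryr2, the calcium release channel of the sarcoplasmic reticulum (1889.8 ± 137 and 1194 ± 93.5), and Pde3a, a cAMP phosphodiesterase (46.8 ± 6.82 and 23 ± 6.22). Among 19 ion channel genes, 8 were lower and 1 higher (12 and 2 when adjusted over the list alone; median -0.28, adjusted p = 0.020; adjusted p = 0.89 with an estimated correlation). Cacna2d1, a calcium channel subunit, differed by -0.49 ± 0.11 (-0.29 after correction for length and GC content, adjusted p = 0.063). Kcna5, a potassium channel, was the 1 higher gene (0.55 ± 0.10). The call of this list was lost without treated wild-type replicate 1 (3 lower and 2 higher, adjusted p = 0.12), and without treated knockout replicate 2 there were 5 lower and 1 higher (median -0.21, adjusted p = 0.047).

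Genes of mitochondrial dynamics and cristae were lower for 8 and higher for 1 of 16 (9 and 1 when adjusted over the list alone), with a median of -0.25 (adjusted p = 0.025; adjusted p = 0.89 with an estimated correlation). Opa1, the substrate of OMA1, stood at 198 ± 17.3 in treated wild-type, 197 ± 9.78 in untreated knockout and 126 ± 16.6 in treated knockout hearts. Between the treated groups its log2 difference was -0.66 ± 0.10 (adjusted p = 0.00086). Immt, a cristae organizer, and Mfn1, a mitofusin of outer membrane fusion, differed by -0.43 ± 0.08 and -0.40 ± 0.08. Of 20 genes of pyruvate entry and the tricarboxylic acid cycle, 10 were lower and 1 higher (median -0.23, adjusted p = 0.018; adjusted p = 0.89 with an estimated correlation). Among them were Dlat (-0.35 ± 0.07), Ogdh (-0.42 ± 0.09) and Dld (-0.43 ± 0.09), which encode parts of the 2-oxoacid dehydrogenase complexes. The median of this list was -0.13 with cyclic loess scaling. The calls of both lists were lost without treated wild-type replicate 1 (adjusted p = 0.072 for each) or replicate 2 (adjusted p = 0.072 and 0.092). Without either the dynamics list had 5 lower and 1 higher and the other list 6 and 1. Without treated knockout replicate 2 these were 4 and 0 (median -0.20) and 6 and 1 (median -0.16), each with adjusted p = 0.047.

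Respiratory chain and ATP synthase genes of the nucleus moved the other way: 41 of 76 were higher and 3 lower (50 and 3 when adjusted over the list alone), with a median of 0.25 (adjusted p = 1.7e-11; adjusted p = 0.89 with an estimated correlation). Ndufa5 and Ndufa13, subunits of complex I, differed by 0.50 ± 0.08 and 0.55 ± 0.09, and Cox7c, of complex IV, by 0.66 ± 0.10. Transcripts of this list were short, with a median length of 913 bases against 3393.5 for all genes. Short transcripts were higher in knockout hearts in general. Among the genes with transcripts of 151 to 1892 bases 408 were higher and 36 lower. Among those of 5530 to 106824 bases 100 were higher and 487 lower. After correction for length and GC content the list had 16 genes higher and 3 lower, with a median of 0.09 (adjusted p = 0.0012). The uncorrected median was 0.16 without treated wild-type replicate 3, with 32 higher and 6 lower (adjusted p = 6.9e-07).

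**Figure D2:**
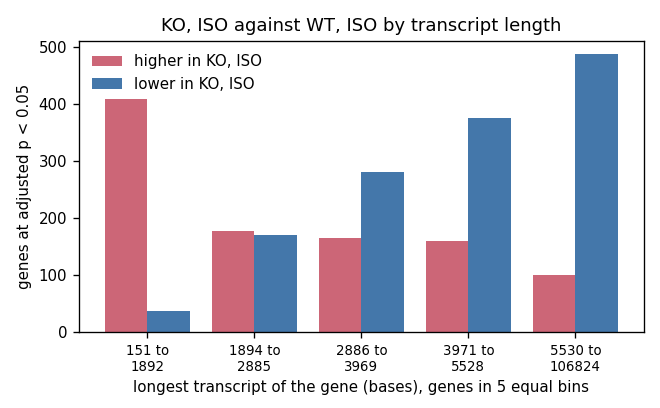
Number of genes past the threshold (y axis) that were higher or lower in treated knockout than in treated wild-type hearts, in 5 equal bins of genes by transcript length in bases (x axis). Higher genes outnumber lower ones in the shortest bin (408 and 36), and lower genes outnumber higher ones in the longest (487 and 100).

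Endothelial markers were higher in treated knockout hearts for 11 of 15 genes and lower for 0 (13 and 0 when adjusted over the list alone; median 0.36, adjusted p = 3.2e-07; adjusted p = 0.89 with an estimated correlation). Fabp4, a fatty acid binding protein of capillaries, stood at 440.2 ± 40.4 in wild-type and 672 ± 72.8 in knockout hearts. Egfl7 and Sox17 differed by 0.65 ± 0.11 and 0.77 ± 0.13. Interferon-stimulated genes were higher for 7 of 18 and lower for 0 (13 and 0 when adjusted over the list alone; median 0.35, adjusted p = 5.9e-05; adjusted p = 0.89 with an estimated correlation). Their examples were the antiviral genes Oas2 (0.83 ± 0.17), Ifit3 (0.47 ± 0.12) and Xaf1 (0.48 ± 0.14). Immediate early genes were higher for 4 of 12 and lower for 0 (median 0.30, adjusted p = 0.0028; adjusted p = 0.89 with an estimated correlation). They included the transcription factors Klf2 (0.62 ± 0.11) and Klf4 (0.42 ± 0.11) and the gene Ier2 (0.60 ± 0.16), whose call was lost after length and GC correction (0.31, adjusted p = 0.16). Fibroblast markers were higher for 4 of 12 and lower for 0 (median 0.14, adjusted p = 0.047; adjusted p = 0.89 with an estimated correlation). Htra3 (0.45 ± 0.07), Pi16 (0.41 ± 0.09) and Gsn (0.42 ± 0.10) led them. The fibroblast call was lost without any 1 of 6 libraries (adjusted p = 0.054 to 0.15): treated wild-type replicates 1 and 2, untreated knockout replicates 1, 2 and 3, and treated knockout replicate 1. It was also lost with the replicate number as a block (adjusted p = 0.054) and by ranks (adjusted p = 0.062). The immediate early call was lost without treated wild-type replicate 2 (adjusted p = 0.058), as were those of Klf4 and Ier2 (adjusted p = 0.058 for each). Without treated knockout replicate 2 the calls of Ier2 and Xaf1 were lost (adjusted p = 0.067 and 0.098), and without treated wild-type replicate 1 that of Xaf1 (adjusted p = 0.052). Leaving out treated knockout replicate 2 left 6 of 14 endothelial (median 0.25, adjusted p = 2.6e-06), 2 interferon-stimulated (median 0.29, adjusted p = 0.0011) and 2 immediate early genes higher (median 0.16, adjusted p = 0.015). Interferon-stimulated genes were also down to 2 without treated wild-type replicate 1 and 4 without treated knockout replicate 3. The immediate early list was down to 1 without treated wild-type replicate 2 (median 0.20). Fibroblast markers had 6 higher without treated wild-type replicate 3 (median 0.28, adjusted p = 0.0011).

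Of the classic genes of hypertrophy and fibrosis, none of Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1 and Postn passed the limma threshold between the treated groups. Nppa, the atrial natriuretic peptide gene, was at 327 ± 447 in wild-type and 100.7 ± 16 in knockout hearts (-0.64 ± 0.69, adjusted p = 0.51). Nppb, the brain natriuretic peptide gene, was at 124 ± 64.5 and 106 ± 11.6. Myh7, the slow myosin of the fetal heart, was at 141 ± 139 and 95.6 ± 8.37. Myh6, the fast myosin of the adult, was at 15895 ± 1723 and 16145 ± 621, and Acta1, skeletal actin, was at 287 ± 189 and 175 ± 31.6. Postn, a matrix protein of activated fibroblasts, was at 504 ± 469 and 235 ± 37.4 (-0.71 ± 0.41, adjusted p = 0.21). Col1a1 and Col3a1, the fibrillar collagens, differed by -0.28 ± 0.28 and -0.33 ± 0.20. The wide SDs came from treated wild-type replicate 3, with Nppa at 842 against 51.8 and 86.0 in its group, Postn at 1043 against 198 and 270, and Myh7 at 301 against 64.3 and 57.5. Without that library Myh7 was higher in knockout hearts by 0.64 (adjusted p = 0.0018) and Nppa by 0.57 (adjusted p = 0.095). Without treated wild-type replicate 1 Postn and Acta1 were lower by log2 differences of -1.18 and -0.95 (adjusted p = 0.040 and 0.023).

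The hypertrophy list had 6 of 15 genes lower and 0 higher (median -0.36, adjusted p = 0.036; adjusted p = 0.89 with an estimated correlation). It was led by Enah (-0.78 ± 0.10), Myocd (-0.53 ± 0.10) and Xirp1 (-0.36 ± 0.08), which act in the actin cytoskeleton and in transcription of muscle genes. That call was lost without treated wild-type replicate 3 (adjusted p = 0.70), treated knockout replicate 1 (adjusted p = 0.054) or treated knockout replicate 3 (adjusted p = 0.10). Of 32 genes of collagens and matrix, 0 passed by limma, with 0 higher and 3 lower at an unadjusted p under 0.05 and 0 by edgeR. Their median was -0.20 (adjusted p = 0.18), and -0.24 after correction for length and GC content (adjusted p = 0.045). Without treated wild-type replicate 3 the matrix list turned to a median of 0.10 with 2 genes higher (adjusted p = 0.037). Its median was -0.42 with 6 genes lower without treated wild-type replicate 1 (adjusted p = 0.00016), -0.31 with 1 lower without replicate 2 (adjusted p = 0.017) and -0.27 without treated knockout replicate 2 (adjusted p = 0.047). Of 28 fatty acid oxidation genes 4 were lower and 1 higher (median -0.11, and -0.026 with cyclic loess scaling; adjusted p = 0.18), with Acsl1 at -0.49 ± 0.11. After the correction the list passed (adjusted p = 0.015), and without treated wild-type replicate 3 it had 15 lower and 0 higher (median -0.26, adjusted p = 0.00026). Its median was weaker without treated knockout replicate 2 (-0.051, adjusted p = 0.68), treated wild-type replicate 1 (-0.044, adjusted p = 0.70) or replicate 2 (-0.054, adjusted p = 0.64). Of 8 tested cell cycle genes 0 passed by limma, 0 at an unadjusted p under 0.05 and 0 by edgeR. Atf4, a transcription factor of the integrated stress response, was at 61.7 ± 0.498 and 71.9 ± 4.71 (0.22 ± 0.07, adjusted p = 0.045). That call was lost without any 1 of 8 libraries (adjusted p = 0.051 to 0.13, all but treated knockout replicate 3) and after length and GC correction (adjusted p = 0.27). Gdf15, below the minimum for testing, was at 0.747 in treated wild-type, 0.220 in untreated knockout and 0.995 in treated knockout hearts.

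**Figure D3:**
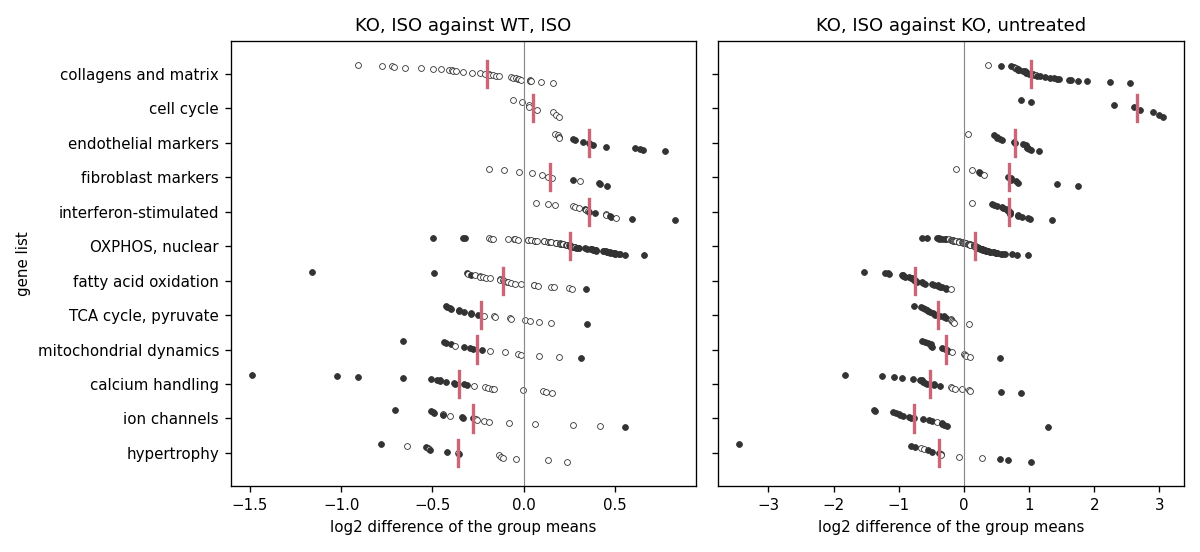
Log2 differences (x axis) of the tested members of 12 fixed gene lists (y axis) between treated knockout and treated wild-type hearts (left) and between treated and untreated knockout hearts (right); filled points passed the threshold over all genes, and red lines are list medians. The matrix list has a median of 1.03 on the right and -0.20 on the left, and the scales of the x axes differ.

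The second comparison sets treated against untreated hearts that lack OMA1. Drug, pump implantation and any difference in the atrial tissue sampled were not separated in it. Rose and fell stand below for higher and lower in the treated group. Treated knockout hearts held more transcripts of dividing cells, of the extracellular matrix and of endothelial cells. They held fewer of fatty acid oxidation, ion channels and atrial myocytes. The calls of these lists were lost with an estimated correlation (adjusted p = 0.33 to 0.38). Proliferation genes were among those that rose most. Top2a, a topoisomerase of dividing cells, rose from 2.79 ± 0.888 to 31 ± 11.2, Mki67, the proliferation marker Ki-67, from 6.14 ± 1.06 to 57.6 ± 21. Ccna2, cyclin A2, rose from 1.44 ± 0.382 to 15 ± 3.46. Prc1, Tpx2, Iqgap3, Kif11 and Anln, genes of the mitotic spindle and cytokinesis, rose by log2 differences of 2.89 ± 0.21, 2.62 ± 0.29, 2.33 ± 0.24, 2.30 ± 0.24 and 2.28 ± 0.20. These 5 ranged from 0.88 to 1.33 with a pseudocount of 10 and from 2.86 to 3.52 by edgeR. With a pseudocount of 10 the log2 differences of Top2a, Mki67 and Ccna2 were 1.65, 2.02 and 1.12, and by edgeR that of Ccna2 was 3.39. Rps13, a ribosomal protein gene with many near-identical copies, showed the largest fitted rise (1.79 ± 1.73 to 37 ± 14.3; 3.93 ± 0.45, 3.32 without untreated knockout replicate 1 and 1.96 with a pseudocount of 10). All 8 tested cell cycle genes rose (median 2.66, adjusted p = 7.4e-07; adjusted p = 0.33 with an estimated correlation). The other 14 of the 22 on that list lay below the minimum and were not tested, and their means were higher in treated knockout hearts for 14 and lower for 0, a count made after the result was seen. In all, 4388 of 8543 genes passed (51.4%), 2043 higher and 2345 lower, of which 176 and 123 changed at least 2-fold. Of the lists 19 passed, none of them with an estimated correlation.

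Collagen and matrix genes rose for 29 of 32 and fell for 0 (30 and 0 when adjusted over the list alone; median 1.03, adjusted p = 8.1e-12; adjusted p = 0.38 with an estimated correlation). Postn rose from 39.3 ± 5.11 to 235 ± 37.4, or 5.85-fold, and Col3a1 from 310.1 ± 26.2 to 654 ± 15.3, or 2.11-fold. Col4a1 and Col4a2, collagens of the basement membrane, rose by 1.06 ± 0.08 and 0.95 ± 0.08, and Sparc, a collagen-binding matrix protein, by 1.46 ± 0.13. Col1a1 rose from 106 ± 5.92 to 188 ± 15.3 (0.82 ± 0.28, adjusted p = 0.025). The call was lost by DESeq2 (adjusted p = 0.094) and robust limma (adjusted p = 0.14). It was also lost without treated knockout replicate 1 or 2 (adjusted p = 0.0501 and 0.073) or untreated knockout replicate 1 or 2 (adjusted p = 0.071 and 0.059). Fibroblast markers rose for 9 of 12 and fell for 0 (10 and 0 when adjusted over the list alone; median 0.69, adjusted p = 4.7e-05; adjusted p = 0.33 with an estimated correlation). Examples were Pi16 at 50.4 ± 0.854 and 138 ± 10.7, Dpt at 0.82 ± 0.08 and Lamc1 at 0.73 ± 0.08.

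Other cells of the heart showed in the same comparison. Endothelial markers rose for 14 of 15 and fell for 0 (median 0.78, adjusted p = 7.3e-09; adjusted p = 0.33 with an estimated correlation). They included Cdh5, VE-cadherin (169 ± 5.37 to 316 ± 17.3), Fabp4 (1.15 ± 0.10) and Pecam1 (0.97 ± 0.08). Markers of smooth muscle and pericytes rose for 8 of 11 and fell for 1 (median 0.34, adjusted p = 0.014; adjusted p = 0.33 with an estimated correlation). Examples were Rgs5 at 0.84 ± 0.09 and Acta2, smooth muscle actin, at 0.85 ± 0.12. Macrophage markers rose for 5 of 11 and fell for 0 (median 0.42, adjusted p = 0.0096; adjusted p = 0.53 with an estimated correlation). Examples were Mrc1 at 0.50 ± 0.10 and Mertk at 0.56 ± 0.11. With 1 library left out the macrophage list had 3 to 9 genes higher (adjusted p = 0.0011 to 0.031) and the smooth muscle list 5 to 8 (adjusted p = 0.0085 to 0.028). Interferon-stimulated genes rose for 17 of 18 and fell for 0 (median 0.69, adjusted p = 7.9e-07; adjusted p = 0.38 with an estimated correlation). Ifit3 (0.89 ± 0.12), Ddx58 (0.82 ± 0.11) and Parp14 (0.70 ± 0.11) rose most clearly. Of 3 tested adipocyte markers, Scd1 fell from 134 ± 100.3 to 14.6 ± 1.7 and Fasn from 77.1 ± 38.9 to 18.3 ± 1.9, both enzymes of fatty acid synthesis that other cells also express. The list call (adjusted p = 0.043; adjusted p = 0.39 with an estimated correlation) was lost without treated wild-type replicate 2 (adjusted p = 0.052), treated knockout replicate 2 (adjusted p = 0.052) or treated knockout replicate 3 (adjusted p = 0.060), and by ranks (adjusted p = 0.0503).

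Of the transcripts of atrial myocytes, Myl7, Myl4, Sln, Bmp10 and Mybphl were near 0 in all 6 treated libraries. The values of the whole list summed to 592 to 1278 in the untreated libraries and 70.6 to 94.0 in the treated ones. Myl7, the atrial regulatory myosin light chain (ENSMUSG00000020469, chromosome 11, 5896637 to 5898782), stood at 199.6 ± 74.7 in untreated knockout hearts, 0.243 ± 0.217 in treated knockout hearts and 0.233 ± 0.0415 in treated wild-type hearts. Myl4, the atrial essential light chain, stood at 311 ± 135, 2.05 ± 0.568 and 1.39 ± 0.336. Sln, sarcolipin, stood at 92.1 ± 40.5 in untreated and 0.027 ± 0.0468 in treated knockout hearts. Bmp10, a growth factor of the atria, had no reads in either treated group and was at least 311-fold lower in treated knockout hearts, from a floor of 3 reads over the group. Mybphl fell from 41.9 ± 18.1 to 0.0616 ± 0.0545, and Dkk3 fell by 3.12 on the log2 scale. Car3, which adipose tissue and skeletal muscle express, and Adcy1 are not in the atrial list. They fell from 42.1 ± 32.2 to 0.477 ± 0.376 and by 2.87 on the log2 scale. Of 9 atrial genes 8 fell and 0 rose (median -4.87, or -5.25 with Bmp10 at its bound; adjusted p = 4.6e-07; adjusted p = 0.33 with an estimated correlation). Without any 1 untreated library the minimum for testing left 4 atrial genes, 3 of them lower (median -1.52 to -1.84, adjusted p = 0.0087 to 0.031). Nppa, which atria express most, fell from 1152 ± 440.1 to 100.7 ± 16 (-3.44 ± 0.69, adjusted p = 0.0011). Fitted log2 values of genes near 0 depend on the pseudocount: that of Myl7 was -7.28 with 1, -8.71 with 0.25 and -4.29 with 10. With 10 those of Myl4, Dkk3 and Adcy1 were -4.65, -2.09 and -1.23.

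**Figure D4:**
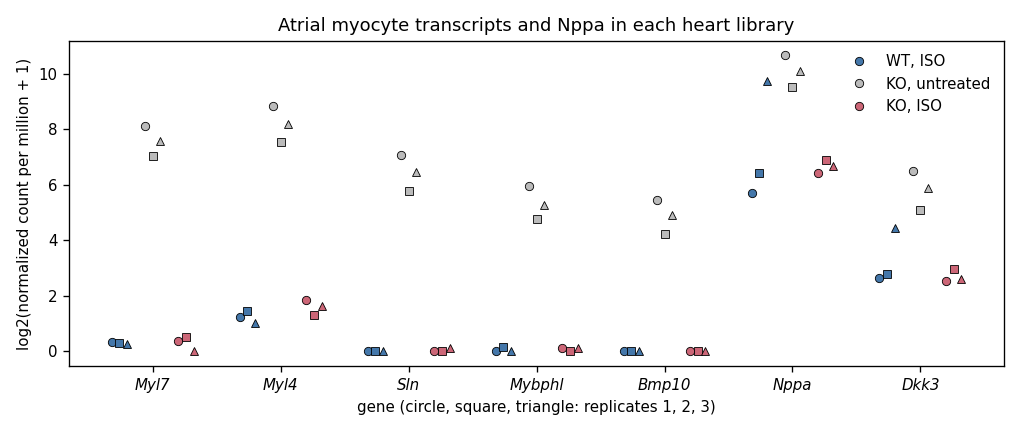
Values of 6 atrial myocyte genes and Nppa, as log2 of normalized counts plus 1 (y axis), in each heart library; points are replicates, colored by group. The 3 untreated libraries lie far above the 6 treated ones for Myl7 and Myl4, while Nppa of treated wild-type replicate 3 (842) lies among the untreated values.

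Fatty acid oxidation fell almost throughout, with 27 of 28 genes lower and 0 higher (median -0.74, adjusted p = 3.7e-10; adjusted p = 0.38 with an estimated correlation). Hadh, a dehydrogenase of the pathway, fell from 561 ± 32 to 250.4 ± 27.3. Acsl1, which activates fatty acids, fell by 0.93 on the log2 scale. Genes of pyruvate entry and the tricarboxylic acid cycle fell for 14 of 20 and rose for 0 (17 and 0 when adjusted over the list alone; median -0.40, adjusted p = 3.5e-05; adjusted p = 0.53 with an estimated correlation). They included Cs, citrate synthase (1282 ± 68.6 to 757 ± 69.5) and Dlat (-0.57 ± 0.07). The median of that list was -0.19 with cyclic loess and -0.23 with quantile scaling. Nuclear respiratory chain genes were 30 higher and 8 lower of 76 (median 0.18, adjusted p = 0.0039; adjusted p = 0.69 with an estimated correlation). Examples were Atp5k at 0.98 ± 0.09 and Ndufa5 at 0.73 ± 0.08. Their median was 0.34 with cyclic loess and 0.32 with quantile scaling, but the call was lost after length and GC correction (median 0.07, adjusted p = 0.15). Genes of the mitochondrial genome rose for 7 of 13 and fell for 0 (median 0.26, adjusted p = 0.013; adjusted p = 0.53 with an estimated correlation). Their leaders were mt-Nd3 at 0.64 ± 0.09 and mt-Atp8 at 0.44 ± 0.09. Their median was 0.093 with quantile scaling, and the call was lost after the correction too (adjusted p = 0.063). Mitochondrial proteases and chaperones fell for 11 of 19 and rose for 0 (median -0.28, adjusted p = 0.0053; adjusted p = 0.53 with an estimated correlation). Trap1 (-0.53 ± 0.07) and Pitrm1 (-0.61 ± 0.09) were among them, and the median was -0.17 with cyclic loess and -0.16 with quantile scaling. Of 16 genes of mitochondrial dynamics 10 fell and 1 rose (median -0.28, adjusted p = 0.034; adjusted p = 0.53 with an estimated correlation). Opa1 fell by 0.65 and Mfn2 by 0.60 on the log2 scale, and Bnip3, a mitophagy receptor, rose by 0.55 ± 0.08. With cyclic loess and quantile scaling the median of the dynamics list was -0.14 and -0.15.

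Ion channel genes fell for 17 of 19 and rose for 1 (18 and 1 when adjusted over the list alone; median -0.77, adjusted p = 6e-06; adjusted p = 0.38 with an estimated correlation). Kcnk3, a background potassium channel that is also in the second set of atrial genes of the closing section, fell from 245 ± 5.08 to 143 ± 6.99 and Scn4b, a sodium channel subunit, from 42.7 ± 2.35 to 21.2 ± 2.96. The channel gene Kcna5 rose from 9.84 ± 0.575 to 25.5 ± 2.83. Calcium handling and adrenergic genes fell for 14 of 22 and rose for 2 (15 and 2 when adjusted over the list alone; median -0.52, adjusted p = 0.00087; adjusted p = 0.38 with an estimated correlation). The median was -0.34 with cyclic loess and -0.26 with quantile scaling. Slc8a1 fell by 1.26 on the log2 scale, Adra1a, an α-adrenergic receptor, from 22.3 ± 2.25 to 5.75 ± 1.94 (log2 difference -1.82, and -1.04 with a pseudocount of 10), and Adcy5, an adenylyl cyclase, by 0.79 on the log2 scale. Immediate early genes rose for 8 of 12 and fell for 2 (median 0.50, adjusted p = 0.013; adjusted p = 0.53 with an estimated correlation). Examples were Klf4 at 1.43 ± 0.11 and Klf2 at 1.08 ± 0.11. Leaving out treated knockout replicate 2 gave 5 higher and 2 lower (median 0.36, adjusted p = 0.039), and leaving out untreated knockout replicate 2 or 3 gave 5 and 1. Genes of apoptosis and necroptosis rose for 6 of 16 and fell for 2 (10 and 2 when adjusted over the list alone; median 0.25, adjusted p = 0.032; adjusted p = 0.33 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose by 1.35 ± 0.16, Casp8 by 1.07 ± 0.14 and Ripk1 by 0.92 ± 0.13. Of the hypertrophy list 3 of 15 rose and 7 fell (adjusted p = 0.13). Nppb was at 87.4 ± 13.9 and 106 ± 11.6, Myh7 at 148 ± 23 and 95.6 ± 8.37, Acta1 at 275 ± 45.5 and 175 ± 31.6 and Myh6 at 18828 ± 1141 and 16145 ± 621. None of the 4 passed (adjusted p = 0.34, 0.24, 0.10 and 0.078). Without treated wild-type replicate 3, which widened the shared spread, Nppb, Myh7, Acta1 and Myh6 passed (adjusted p = 0.036, 0.00018, 0.0036 and 0.031), and without treated wild-type replicate 1 Acta1 did (adjusted p = 0.028). Fitted on the 2 knockout groups alone all 4 passed (adjusted p = 0.043, 0.00033, 0.0010 and 0.034). Acta1 passed with array weights (adjusted p = 0.0071). Myh6 passed by edgeR, DESeq2, robust limma, array weights, the replicate block, cyclic loess and quantile scaling as well (adjusted p = 4.6e-06 to 0.048).

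Treated wild-type and untreated knockout hearts differ in genotype and in treatment, so their differences belong to neither alone. They serve to show where the treated wild-type hearts stood against the untreated group at hand. Treated wild-type hearts too had more matrix and proliferation transcripts and fewer atrial and fatty acid oxidation transcripts than untreated knockout hearts. The calls of these lists were lost with an estimated correlation (adjusted p = 0.40 to 0.42). Postn stood 9.56-fold higher (3.26 ± 0.41; 5.79-fold without treated wild-type replicate 3), Top2a 8.35-fold and Cilp, a matrix protein of cartilage and fibrosis, 7.83-fold (4.70-fold without that replicate). Tom1 had no reads in untreated hearts and was at least 183-fold higher in treated wild-type hearts, while treated knockout hearts held 7.04 ± 10.5. Rps13 differed by 3.14 ± 0.45 (2.52 without untreated knockout replicate 1). Sln had no reads in treated wild-type hearts and was at least 912-fold lower. Myl7, Myl4, Mybphl and Car3 differed by -7.28 ± 0.25, -6.95 ± 0.25, -5.29 ± 0.35 and -5.06 ± 0.44, or -4.29, -4.73, -2.31 and -2.20 with a pseudocount of 10. With that pseudocount those of Top2a, Cilp and Rps13 were 1.65, 2.13 and 1.36. In all, 2839 of 8543 genes passed (33.2%), 1399 higher and 1440 lower in treated wild-type hearts. Of the lists 15 passed, none of them with an estimated correlation.

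The lists of collagens and matrix (31 of 32 higher, 0 lower, 32 when adjusted over the list alone; median 1.27, adjusted p = 2e-19) and of the cell cycle (8 of 8 tested genes higher, with 14 more not tested; median 2.61, adjusted p = 7.4e-09) passed, with adjusted p = 0.42 and 0.40 with an estimated correlation. Their members included Fbn1 (1.77 ± 0.14), Col4a1 (1.03 ± 0.08), Col3a1 (1.41 ± 0.20) and Mki67 (2.80 ± 0.20; 1.85 with a pseudocount of 10). Col1a1 differed by 1.11 ± 0.28 (adjusted p = 0.0085; 0.084 by robust limma). Fatty acid oxidation (23 of 28 lower, 0 higher; median -0.52, adjusted p = 1.3e-11) and atrial genes (8 of 9 lower, 0 higher; median -4.87, or -5.29 with genes at their bounds, adjusted p = 2.4e-11) were lower, each with adjusted p = 0.42 with an estimated correlation. Hadh differed by -1.03 ± 0.11 and Nppa by -2.80 ± 0.69 (adjusted p = 0.0075). The Nppa call was lost by edgeR, DESeq2 and robust limma (adjusted p = 0.077, 0.16 and 0.084), and its log2 difference was -4.02 without treated wild-type replicate 3 and -2.02 without replicate 1. Endothelial (10 of 15 higher, 0 lower; adjusted p = 4.8e-05; Cdh5 0.71 ± 0.07, Pecam1 0.69 ± 0.08), smooth muscle (4 of 11 higher, 0 lower; adjusted p = 0.017; Acta2 1.22 ± 0.12, Rgs5 0.79 ± 0.09) and fibroblast markers (9 of 12 higher, 2 lower; adjusted p = 0.0015; Lamc1 0.92 ± 0.08, Pi16 104 ± 14.3 against 50.4 ± 0.854) passed, each with adjusted p = 0.42 with an estimated correlation.

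Ion channels (12 of 19 lower, 1 higher, 13 and 2 when adjusted over the list alone; adjusted p = 0.0006, and adjusted p = 0.62 with an estimated correlation; Scn4b -1.04 ± 0.10) and the tricarboxylic acid cycle list (10 of 20 lower, 0 higher, 11 lower when adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.65 with an estimated correlation; Idh2 -0.59 ± 0.10) were lower in treated wild-type hearts. Interferon-stimulated genes were higher for 7 of 18 and lower for 0 (8 higher when adjusted over the list alone; adjusted p = 0.0027, and adjusted p = 0.63 with an estimated correlation; Ddx58 0.69 ± 0.11, Ifi44 10.3 against 4.88). Adult sarcomere genes were lower for 6 and higher for 1 of 16 (adjusted p = 0.017, and adjusted p = 0.63 with an estimated correlation), with Tcap (644 ± 35.1 in untreated, 287 ± 42 in treated wild-type hearts) and Myom2 (-1.27 ± 0.13). The sarcomere call was lost after length and GC correction (adjusted p = 0.070), and the median of -0.19 was -0.090 with cyclic loess and -0.048 with quantile scaling. That of the tricarboxylic acid cycle list, -0.23, was -0.13 and -0.14. It was -0.17 without treated wild-type replicate 3, with 4 lower and 1 higher (adjusted p = 0.019), and 4 were lower without untreated knockout replicate 1 or 2 (adjusted p = 0.0027 and 0.0049). Interferon-stimulated genes were higher for 2 without untreated knockout replicate 1 (adjusted p = 0.032) and for 4 without replicate 2 or treated wild-type replicate 2 (adjusted p = 0.0011 and 0.0073). Of the adipocyte markers Scd1 and Fasn differed by -2.83 ± 0.35 and -1.61 ± 0.23 (adjusted p = 0.021, and adjusted p = 0.42 with an estimated correlation). Mitochondrial proteases and chaperones (9 of 19 lower, 0 higher, 10 lower when adjusted over the list alone; adjusted p = 0.017; Spg7 -0.37 ± 0.08, Hspd1 -0.46 ± 0.10), respiratory chain genes (13 of 76 lower, 4 higher, 13 and 3 when adjusted over the list alone; adjusted p = 0.024; Cox6a2 -0.67 ± 0.09, Ndufv1 -0.49 ± 0.09) and macrophage markers (4 of 11 higher, 0 lower; adjusted p = 0.036; Mrc1 0.61 ± 0.10, F13a1 0.43 ± 0.11) passed as well, with adjusted p = 0.65, 0.88 and 0.65 with an estimated correlation. Without treated wild-type replicate 3 these 3 calls were lost (adjusted p = 0.093, 0.94 and 0.35). The respiratory chain call was also lost without untreated knockout replicate 1 (adjusted p = 0.082) and after length and GC correction (adjusted p = 0.45). It had 9 lower and 8 higher without treated wild-type replicate 3, with a median of 0.0025. Its median of -0.11 was -0.0046 with cyclic loess and -0.0038 with quantile scaling. The macrophage call was also lost without untreated knockout replicate 1 or 2 (adjusted p = 0.13 and 0.072), where proteases and chaperones had 5 and 4 lower (adjusted p = 0.032 and 0.017). Oma1 itself differed by 1.32 ± 0.14 and Atf4 by 0.41 ± 0.07. Opa1 (0.01 ± 0.10, adjusted p = 0.94), Nppb (0.40 ± 0.24), Myh7 (-0.49 ± 0.43), Myh6 (-0.25 ± 0.10) and Acta1 (-0.13 ± 0.32) did not pass. Without treated wild-type replicate 3 Myh7 and Acta1 were lower by log2 differences of -1.26 and -0.63 (adjusted p = 3.3e-06 and 0.019), and without treated wild-type replicate 1 Myh6 by -0.33 (adjusted p = 0.033). Myh7 passed with array weights (adjusted p = 0.045). Myh6 passed by edgeR, DESeq2, voom, robust limma, the replicate block, cyclic loess and quantile scaling (adjusted p = 1.0e-05 to 0.041).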

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

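The number of genes past the threshold moved by more than 1.5 times under few of the alternatives. With a minimum value of 100, which left 1188 genes to test, 628 passed between the treated groups, 828 between the knockout groups and 540 between treated wild-type and untreated knockout hearts. Asking also for a log2 difference of at least 1 left 27, 299 and 185. At an adjusted p below 0.01 959 passed between the treated groups and 1642 between treated wild-type and untreated knockout hearts. After correction for transcript length and GC content the first had 1574, of which 1204 were shared with the 2379. Leaving out each library in turn gave 1336 to 2382 genes for the first comparison, 3574 to 4605 between the knockout groups and 1957 to 3087 between treated wild-type and untreated knockout hearts. The lowest of the first came without treated knockout replicate 2, and the cause was not tested. Whole reads were recovered for 100% of values, and edgeR on them called 2429, 4347 and 2799 genes. DESeq2, voom and edgeR together gave 2035 to 2479, 3841 to 4357 and 2364 to 2799. With the replicate number as a block there were 2258, 4316 and 2755. Deviations of libraries with the same number correlated by -0.14 to 0.18, so the numbers were not taken to pair the samples. The planned runs of voom, edgeR and DESeq2 on the values themselves were not done, because the values are normalized, and were replaced by runs on recovered reads.

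Of the lists, 10, 19 and 15 passed with the preset correlation and 0, 0 and 0 with an estimated one, where the lowest adjusted p was 0.89, 0.33 and 0.40. The cause of the loss was not tested. Leaving out libraries gave 7 to 14, 18 to 21 and 13 to 17 lists, the block 9, 19 and 15, ranks 9, 18 and 15, and the length and GC correction 14, 18 and 17.

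Of 183 gene results under all alternatives, 4512 of 4597 values kept their call and direction, 34 were stronger, 31 weaker and 20 reversed. All reversed values belonged to genes that had not passed. Many of the genes were named for a large change or a small p in these same data. The share that kept their call therefore does not show how calls of all genes hold. A kept call also takes no account of size. Bmp10 kept its call between the knockout groups at log2 differences of -1.95 with a pseudocount of 10 and -11.1 by edgeR. Between the treated groups, leaving out libraries moved Nppa from -1.43 to 0.57, Nppb from -0.35 to 0.28, Myh7 from -0.54 to 0.64, Myh6 from -0.044 to 0.11, Col1a1 from -0.55 to 0.21, Col3a1 from -0.55 to 0.0082 and Postn from -1.18 to 0.015. All 7 turned without treated wild-type replicate 3, and the cause was not tested. Array weights turned Nppb to 0.017 and Myh7 to 0.26, and cyclic loess turned Myh6 to -0.013. Between treated wild-type and untreated knockout hearts, Acta1 ranged from -0.63 to 0.29 with libraries left out, turning without treated wild-type replicate 1. It turned to 0.0705 by edgeR, 0.0686 by edgeR with size factors, 0.0691 by DESeq2 and 0.0255 after length and GC correction. Opa1 ranged from -0.044 to 0.081, with -0.00404 without treated wild-type replicate 1 and -0.0245 without untreated knockout replicate 3. It was -0.00726 with median centring and -0.11 after length and GC correction. Scaling moved the median of all genes by at most 0.018 but those of some lists by more than 1.5 times. Between the knockout groups the respiratory chain list went from 0.18 to 0.34, calcium handling from -0.52 to -0.26, the tricarboxylic acid cycle from -0.40 to -0.19 and the mitochondrial genome from 0.26 to 0.093. The list tests were not run under the other scalings.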

Other observations

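Some clock genes differed between treated and untreated hearts, though their list passed in neither comparison with the untreated group. Nr1d1, a clock repressor, stood at 102 ± 6.81 in untreated knockout hearts, 46.3 ± 1.62 in treated wild-type and 43.9 ± 9.65 in treated knockout hearts. Dbp and Tef, output factors of the clock, fell in knockout hearts by 1.54 and by 0.95 on the log2 scale, and Arntl, the activator, rose by 0.71 ± 0.09. In treated wild-type against untreated knockout hearts the log2 differences of Nr1d1, Dbp, Tef and Arntl were -1.13, -1.70, -0.75 and 0.77. With a pseudocount of 10 that of Dbp was -1.02, and -0.94 between the knockout groups. Of 15 clock genes 4 rose and 10 fell between the knockout groups (median -0.40, adjusted p = 0.13), and 6 fell without untreated knockout replicate 1. In treated wild-type against untreated knockout hearts, which differ in genotype too, 3 were higher and 7 lower (median -0.14, adjusted p = 0.16). The hour of dissection is not given in the sources used here.

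Genes of the integrated stress response rose for 7 of 12 and fell for 2 between the knockout groups (7 and 3 when adjusted over the list alone; median 0.43, adjusted p = 0.059). Without any 1 untreated library the minimum for testing left 11 genes, and the list passed (adjusted p = 0.013 to 0.026). The gene lost reached the minimum only with that library, so this pass cannot be set against the 0.059 of all 12. Without treated knockout replicate 1 the adjusted p of the list was 0.072. Atf5, a transcription factor of the mitochondrial stress response, rose from 26.4 ± 0.898 to 46.8 ± 5, and Atf4 from 46.3 ± 2.72 to 71.9 ± 4.71. Between the treated groups the list had 3 of 12 higher and 3 lower (4 and 3 when adjusted over the list alone; adjusted p = 0.61). Near Oma1 on chromosome 4, Prkaa2, a catalytic subunit of the energy sensor AMPK, was at 165 ± 6.29 in treated wild-type, 173 ± 1.41 in untreated knockout and 93 ± 20.4 in treated knockout hearts. Hook1 was at 17.9 ± 2.64, 19.3 ± 0.527 and 10.6 ± 1.44. Both genes were lower in treated than in untreated knockout hearts, where they stood close to the treated wild-type values.

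The fall of atrial transcripts was examined with 2 tests, of which the comparison of the treated groups was chosen after the result was seen. The sums of the atrial list were 1278, 592 and 857 in the untreated libraries and 70.6 to 94.0 in the treated ones. In a second set of 10 atrial genes, 8 were lower in treated knockout hearts, with a median of -0.83, while 3 of 7 ventricular markers were lower, with a median of -0.36. Between the treated groups the median of the atrial list was 0.032. Atria left out of the treated samples at dissection may account for the pattern, as may loss of atrial transcripts under isoproterenol, and these 2 explanations cannot be told apart here.

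The higher respiratory chain genes and lower calcium handling genes of treated knockout hearts were examined for a bias by transcript length and GC content, with the bounds of the tests set before they were run. Across genes the log2 difference correlated with length (Spearman rho = -0.34) and with GC content (rho = 0.39). Without treated knockout replicate 2 these were -0.37 and 0.39, so that library alone was not the cause. Against the mean of all libraries, treated wild-type replicates 1, 2 and 3 had rho of 0.38, 0.05 and 0.33 with length. With GC content theirs were -0.40, -0.34 and -0.33. Treated knockout libraries had -0.22 to -0.17 with length and 0.11 to 0.22 with GC content. Untreated ones had -0.04 to 0.03 and 0.07 to 0.11. The trend thus lay in both treated groups, and its cause was not tested. After correction for length and GC content the median of the calcium handling list was -0.27, with 11 of 22 lower and 0 higher. A bias of the form that this correction removes was therefore not the whole cause of the lower values. The correction took the longest annotated coding transcript of each gene where it had one, so other forms of such a bias were not excluded. The median of the respiratory chain list was 0.093 after the correction. Whether a bias made the rest of it cannot be told apart from a change in the hearts.

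Genes that followed genotype were examined for strain differences, with the bounds of both tests set before they were run. Such genes passed in both knockout groups against treated wild-type hearts, by at least 0.5 on the log2 scale, but not between the knockout groups. Of them 21 were higher and 11 lower in knockout hearts, though the shared wild-type libraries may give part of this. Independent calls would give an overlap of 10.3 and 17.1. Those values leave out the condition between the knockout groups, so they cannot be set against the 21 and 11. Simulations with the shared libraries and no change gave means of 0.05 and 0. Few genes are called where nothing changes, so these means cannot show how much overlap the shared libraries give. Of 52 tested genes within 10 Mb of Oma1, 2 followed genotype, against 29 of 8441 elsewhere (two-sided Fisher's exact p = 0.015). Echdc2 was higher and Tdeanc2 lower, and the share would fit a linked stretch from another strain. Of all 31 such genes other than Oma1, 4 had another within 1 Mb (permutation p = 0.17), so further strain segments cannot be told apart from scattered genes, and strain could contribute to any difference between genotypes.

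Each comparison of 6 libraries allows 10 splits into 3 and 3, too few for a share under 0.05. In each of the 3 comparisons 1 of 10 splits, the real one, reached the count of 2379, 4388 or 2839 genes, and the highest other count was 0. Without treated knockout replicate 2, which had the largest share of mitochondrial transcripts, 5 of 6 erythroid genes were lower in treated knockout than in treated wild-type hearts (median -1.10, adjusted p = 0.00085) and 5 of 6 lower than in untreated knockout hearts (median -1.37, adjusted p = 0.0049). With that library 0 of 6 passed by limma in either comparison, with 0 and 2 at an unadjusted p under 0.05 and 0 by edgeR.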
